A study of Homo sapiens with 15 samples.

How the data were processed

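RNA of A549 cells grown in F12K medium with charcoal-treated serum was labelled with biotin and hybridized to Affymetrix arrays, per the labels' protocols, with 15 arrays in 5 groups of 3. The groups were non-treated cells, dexamethasone for 6 hours, and dexamethasone for 6 hours with mifepristone, match polyamide or mismatch polyamide for 48 hours. Doses are not given in the sources used here, and the labels do not say whether replicate arrays came from separate cultures. The deposited values were intensity signals on a linear scale, 1 per probe set and array, made by the authors with MAS5 per the submitters' processing notes, with the version and the scaling target not given in the sources used here.

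The table held 54675 probe sets. The arrays were not scaled alike, since their 2% trimmed means ran from 87.2 to 147.2 and their medians from 14.8 to 24.5. Mean trimmed means were 96.3 (SD 7.85) for non-treated, 97.4 (SD 9.14) for dexamethasone, 133.9 (SD 14.1) for mifepristone, 100.5 (SD 8.99) for match and 112.7 (SD 23.0) for mismatch, 3 arrays each. The design, fixed before the data were examined, asked for no further normalization if the arrays were already scaled alike. Because they were not, signals were quantile normalized, and log2(signal + 16) was taken. The added 16 keeps low signals from dominating, and it means that the log2 changes and folds printed here understate the change of genes with low signals. Mean signals of genes are quantile-normalized signals on the linear scale, and those of control probe sets are signals as deposited. With 3 arrays per group the number of arrays limits the precision.

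A probe set was tested if at least 3 of the 15 arrays lay above the 40th percentile of their own array, which kept 39744 probe sets (72.7%) after the 62 Affymetrix control probe sets were left out. Linear models with 1 coefficient per group were fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend in the mean (10 residual and 9.36 prior degrees of freedom). P-values were adjusted by the method of Benjamini and Hochberg over the probe sets tested in each comparison, and a probe set was called changed at an adjusted p under 0.05. The comparisons were dexamethasone with non-treated, each compound with dexamethasone alone, match with mismatch, and match with mifepristone. The comparison of mifepristone plus dexamethasone with non-treated cells was added after the results were seen.

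Probe sets were named from a table of the genes of each probe set, which named 42898 of them, 41097 with 1 symbol and 1801 with several, and left 11777 without a named gene. Each gene was represented by 1 probe set that carries its symbol alone, taking those not ending in _x_at first and then the highest mean, which gave 16358 genes. The text names the 8 genes most raised and the 8 most lowered in each comparison among called genes whose arrays were fully separated between the groups, the fixed genes FKBP5, TSC22D3, DUSP1, SGK1, KLF9, ANGPTL4, ZBTB16 and CXCL8 (PER1 was fixed too, but no tested probe set carries its symbol alone, and 1 further fixed gene is not reported here), and up to 4 members of each list with the smallest adjusted p. A few further members of the lists, the genes quoted in a second comparison, and those in the mifepristone comparison with non-treated cells were chosen after their values were seen.

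Lists of genes written before the data were examined were tested as sets with camera of limma at a preset correlation of 0.01, with adjustment over the 20 lists of each comparison, and again with a correlation estimated from the arrays. The lists covered genes induced by glucocorticoids (GR-induced), inflammatory genes repressed by them, metallothioneins, p53 targets, cell cycle, cholesterol synthesis, hypoxia, ER stress and ATF4, interferon response, NRF2 targets, the circadian clock, immediate early genes, TGF-beta and matrix, epithelial and lung genes, drug metabolism, transcription machinery, ribosomal proteins, leukocyte markers, fibroblast markers, and steroid receptors and co-regulators. Some genes stand in more than 1 list. Members were counted as higher, lower or not past the test by the adjusted p over all probe sets, and again by a p-value adjusted over the list alone.

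Probe sets changed at least 2-fold by dexamethasone were counted as moved back when a compound changed them the opposite way with a passed test. Counts expected without any effect of the compound came from 20 simulations that share the dexamethasone arrays. The difference between the polyamides was summarised over the same probe sets by its median and by camera. Gene spans were taken from the RefSeq annotation of GRCh38.p14, matched for 16334 of 16358 genes (99.9%), and were used only as lengths.

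On simulated data made from the 39744 probe sets of the comparison of dexamethasone with non-treated, the fit recovered 30.3% of changes at 1.5-fold, 74.6% at 2-fold and 96.7% at 4-fold, with 4.44% of calls false, and camera called the shifted list and 0 of 19 unchanged lists. The simulated probe sets varied independently of each other, and far fewer were changed than were called in the data. In the real lists the estimated correlation reached 0.106 (interferon response). These rates and the list result therefore need not carry over to the real arrays. The alternatives tried were median centring, pseudocounts of 1 and 64, no filter, a stricter filter on the mean signal at the 60th percentile, no variance trend, array weights, only the 6 arrays compared, the replicate number as a block, leaving out each array in turn, a 1.5-fold selection, the median of all probe sets of a gene, and the estimated correlation. After the data had been seen, the signals as deposited, scaling to a common 2% trimmed mean, and scaling on the hybridization spike-in probe sets were added. Each comparison was also repeated over all splits of its 6 arrays into 3 and 3, of which there are 10, so that the smallest possible share is 0.1.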

Results

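Gene expression was measured in A549 cells, a human lung adenocarcinoma epithelial line, on 15 Affymetrix arrays in 5 groups of 3. Cells were left non-treated, were given dexamethasone, a synthetic glucocorticoid, for 6 hours, or were given dexamethasone for 6 hours together with 1 of 3 compounds for 48 hours. The compounds were mifepristone, an antagonist of the glucocorticoid receptor, and 2 polyamides, synthetic ligands of the minor groove of DNA. The polyamides were labelled match and mismatch, and the series concerns a polyamide directed to the glucocorticoid response element, the DNA sequence that the activated receptor binds. Across the 39744 probe sets tested, the first principal component held 39.5% of the variance and set the polyamide arrays apart, with scores of 60.3 to 66.8 for match and 31.8 to 35.5 for mismatch against -36.6 to -30.1 for the other 9 arrays. Pairs of arrays correlated at r = 0.927 to 0.940 within groups and at r = 0.883 to 0.939 between groups on the log2 deposited signals. The number of arrays, 3 per group, limits the precision of each value. Nothing in the labels says that the arrays came from separate cultures, so each p-value measures only the spread between these arrays, which may be technical.

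The comparison of dexamethasone with non-treated cells asked which transcripts the hormone changed within 6 hours. FKBP5, which encodes a co-chaperone of the glucocorticoid receptor, rose by 3.48 log2 units (SE 0.07, 3 arrays per group; limma adjusted p = 3.3e-17), from a mean signal of 228 to 2706. CDKN1C, a cyclin-dependent kinase inhibitor, rose by 3.61 (SE 0.12), from 17.6 to 393, and TSC22D3, which encodes the anti-inflammatory protein GILZ, rose by 3.01 (SE 0.09). The transcripts of the mitochondrial co-chaperone DNAJC15 (3.45, SE 0.21), the transcription factor TFCP2L1 (3.44, SE 0.11), the lipoprotein lipase inhibitor ANGPTL4 (3.24, SE 0.16), the small GTPase RRAD (3.11, SE 0.18) and the lipid-droplet protein CIDEC (3.03, SE 0.13) were the others among the 8 largest rises with fully separated arrays. The 8 largest falls of that kind were in the cytokine TNFSF15 (-2.46, SE 0.14), the cytokine IL11 (-2.28, SE 0.22), the vitamin D 24-hydroxylase CYP24A1 (-2.21, SE 0.10; 2729 to 581), the sialyltransferase ST8SIA4 (-2.06, SE 0.14), TM4SF20 (-1.84, SE 0.12), the nuclear receptor NR4A2 (-1.82, SE 0.11), CNNM4 (-1.78, SE 0.23) and the early response gene IER3 (-1.66, SE 0.07). Adjusted p-values of these 16 genes ran up to 2.8e-05, that of CNNM4. Known targets outside these 16 rose as well, with DUSP1, a phosphatase that switches off MAP kinases, at 1.40 (SE 0.05), KLF9 at 1.24 (SE 0.18), SGK1 at 0.96 (SE 0.10) and ERRFI1 at 1.65 (SE 0.05). ZBTB16 did not pass the test (-0.09, 95% CI -0.70 to 0.52, adjusted p = 0.94). CXCL8, the neutrophil chemokine, did not pass either (-0.35, SE 0.21, adjusted p = 0.48). A second tested probe set of CXCL8 was lower at -0.82 (adjusted p = 0.0154), and that one stood for the gene under the stricter filter (adjusted p = 0.0113). Probe sets of the same gene also differed for DUSP1, at 2.68 and at 0.34 (adjusted p = 0.321), for KLF9, at 0.37 (adjusted p = 0.588), and for TSC22D3, at 2.23 and at 0.11 (adjusted p = 0.878), while those of FKBP5 (4.20 and 3.47) and ANGPTL4 (3.66) rose as well. The other probe set of TNFSF15 and of IL11 was not called.

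**Figure D1:**
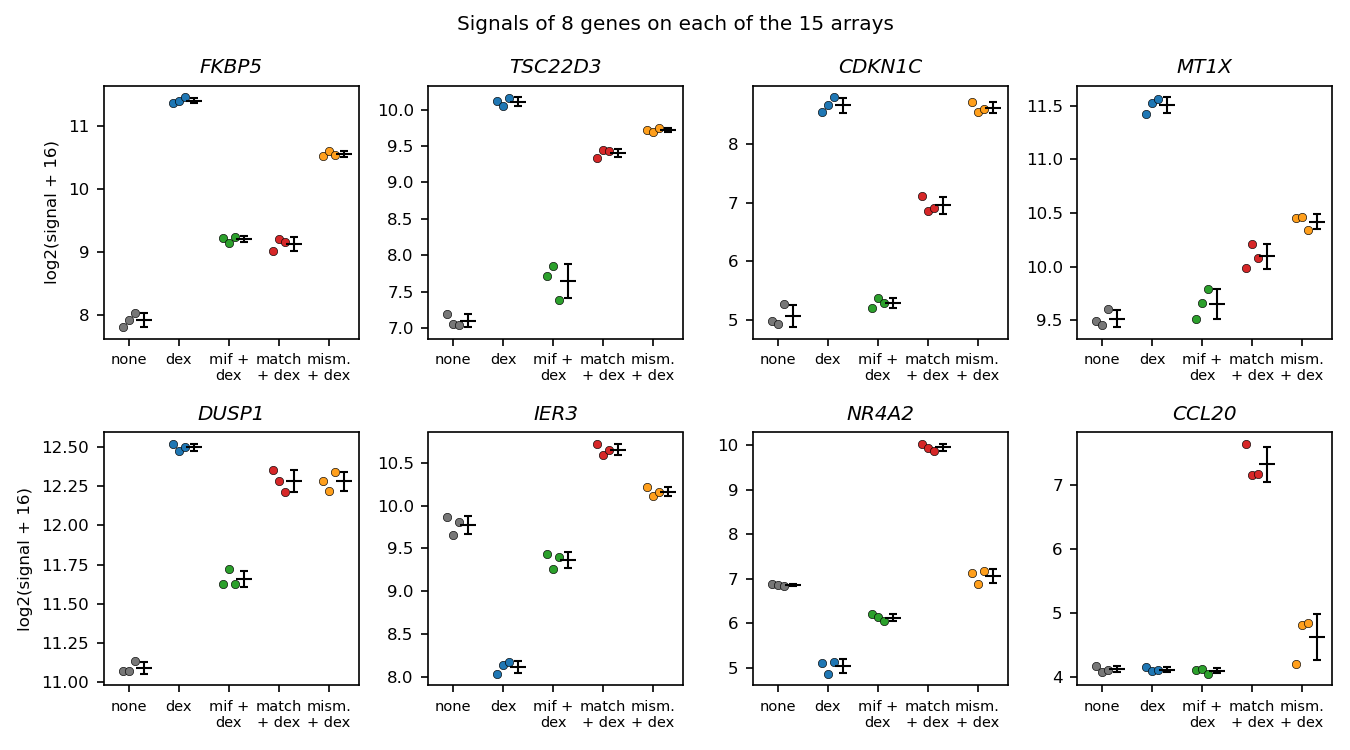
Signals of 8 genes on each of the 15 arrays; points are arrays, the mark and bar are the mean ± SD of 3 arrays, and the y axis is log2(signal + 16). FKBP5, TSC22D3, CDKN1C, MT1X and DUSP1 were higher with dexamethasone, IER3 and NR4A2 were lower with dexamethasone and higher with either polyamide, and CCL20 was at 145 in mean signal with the match polyamide.

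In total 1933 of 39744 probe sets (4.86%) changed with dexamethasone, 1021 higher and 912 lower, and 372 of these changed at least 2-fold, 290 higher and 82 lower. The count fell to 814 on the signals as deposited (564 higher, 250 lower) and to 767 with spike-in scaling (452 and 315). Of 33 tested members of the glucocorticoid-induced list, 28 rose, 0 fell and 5 did not pass, and the counts were the same when adjusted over the list alone; the median was 1.35 and the list shifted as a set (camera adjusted p = 2.3e-71). Among its members RGS2 rose by 2.44, ZFP36, which destabilises cytokine transcripts, by 2.16, IGFBP1 by 2.00 and NFKBIA, the inhibitor of NF-kappaB, by 1.11. The metallothioneins, small metal-binding proteins, rose in 6 of 7 members with 0 lower and 1 not past the test (6 and 0 when adjusted over the list alone; median 1.91, adjusted p = 6.0e-22). MT1H stood at 2.26, MT1F at 2.15 and MT1X at 1.99. The inflammatory list moved down, with 0 of 22 members higher, 10 lower and 12 not past the test (0 and 11 when adjusted over the list alone; median -0.36, adjusted p = 6.3e-09). The inducible cyclooxygenase PTGS2 (-1.36, SE 0.10), the urokinase receptor PLAUR (-0.99, SE 0.12) and the chemokine CCL2 (-1.35) fell. The list of NRF2 targets, the antioxidant genes, also moved down (0 of 20 higher, 8 lower, 12 not past the test; 0 and 9 when adjusted over the list alone; median -0.17, adjusted p = 3.6e-11). Haem oxygenase HMOX1 (-1.54, SE 0.12), SRXN1 (-0.88) and the glutathione synthesis genes GCLM (-0.78) and GCLC (-0.75) fell. With an estimated correlation between members these 4 lists remained past the threshold (adjusted p from 2.9e-08 for the glucocorticoid-induced list to 0.00095). Adjusted p-values of the other 16 lists lay between 0.19 and 0.96. The immediate early list was mixed, with 7 members higher, among them MCL1 (1.32) and KLF4 (1.22), and 8 lower (9 when adjusted over the list alone), among them IER2 (-1.50); its median was 0.01, its mean -0.07 and its adjusted p = 0.81. Single genes of other lists changed too. GADD45A (1.58, SE 0.08) and TP53I3 (0.94) of the p53 list, NDRG1 (1.29), DDIT4 (0.94), the clock genes PER2 (1.17) and NR1D2 (1.09), the matricellular proteins CCN2 (1.38) and THBS1 (1.06) and the mucin MUC1 (0.88) rose. SLC7A11, the cystine transporter (-1.61), TGFB2 (-1.45), PMEPA1 (-0.95), PFKFB3 (-0.91) and ELF3 (-0.70) fell. NR3C1, the glucocorticoid receptor itself, was lower by this fit (-0.34, SE 0.08, adjusted p = 0.009), but the call was lost on the signals as deposited (0.662), with spike-in scaling (0.419), without a variance trend (0.0864) and without dexamethasone replicate 2 (0.0811).

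Mifepristone given with dexamethasone was compared with dexamethasone alone to ask how far a receptor antagonist takes these changes back. CDKN1C was lower by 3.38 log2 units (SE 0.12), TSC22D3 by 2.46 (SE 0.09) and FKBP5 by 2.20 (SE 0.07; 2706 to 576). DNAJC15 (-3.32, SE 0.21), RRAD (-3.09, SE 0.18), TFCP2L1 (-2.51, SE 0.11), MT1H (-2.21, SE 0.13) and FGD4 (-2.19, SE 0.13) were the other genes among the 8 most lowered. The 8 most raised were TNFSF15 (2.14, SE 0.14), CYP24A1 (2.01, SE 0.10), ST8SIA4 (1.89, SE 0.14), RND1 (1.69, SE 0.39, adjusted p = 0.015), TM4SF20 (1.68, SE 0.12), HMOX1 (1.39, SE 0.12), SLC7A11 (1.35, SE 0.08) and KCNIP2-AS1 (1.34, SE 0.25). RND1 rested on few arrays, since its call was lost without dexamethasone replicate 1 (adjusted p = 0.105) or 3 (0.0737), without mifepristone replicate 1 (0.0686) or 3 (0.0711), and without a variance trend (0.0833). ANGPTL4 (-2.08, SE 0.16), SGK1 (-1.20, SE 0.10), KLF9 (-0.92, SE 0.18) and DUSP1 (-0.84, SE 0.05) were lower than with dexamethasone alone. ZBTB16 (-0.32, SE 0.29, adjusted p = 0.77) and CXCL8 (0.33, SE 0.21, adjusted p = 0.60) did not pass the test. Further probe sets of DUSP1 stood at -1.35 and at -0.30 (adjusted p = 0.463), of KLF9 at -0.11 (adjusted p = 0.934) and of TSC22D3 at -1.99 and at -0.32 (adjusted p = 0.578), and the other probe set of TNFSF15 was not called.

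The probe sets changed by mifepristone numbered 1412 (3.55%), 640 higher and 772 lower, with 52 higher and 178 lower by 2-fold or more. Count and direction depended on array scaling, with 8142 changed on the signals as deposited, 7910 of them higher, and 12838 with spike-in scaling, 12616 of them higher. The glucocorticoid-induced list fell in 25 of 33 members with 0 higher and 8 not past the test (27 and 0 when adjusted over the list alone; median -0.999, camera adjusted p = 1.3e-61). RGS2 stood at -2.11. Metallothioneins fell in 6 of 7 members, with 0 higher and 1 not past the test and the same counts when adjusted over the list alone (median -1.71, adjusted p = 4.0e-22), MT1X at -1.85 and MT2A at -1.62 among them. NRF2 targets rose in 10 of 20 members, with 0 lower and 10 not past the test and the same counts when adjusted over the list alone (median 0.18, adjusted p = 2.6e-14). GCLC (0.84), SRXN1 (0.71) and GCLM (0.65) were among its members. The inflammatory list rose in 6 of 22 members, with 0 lower and 16 not past the test (7 and 1 when adjusted over the list alone; median 0.20, adjusted p = 0.0005). IER3 (1.24), PTGS2 (1.24), IL11 (1.08) and PLAUR (0.61) were among its members. These 4 lists also passed with an estimated correlation (adjusted p from 6.0e-08 to 0.018), and the other 16 lists had adjusted p-values of 0.14 to 0.91. Genes outside those lists that dexamethasone had moved went the other way here, with CCN2 at -1.60, GADD45A at -1.49, KLF4 at -1.24, NDRG1 at -1.20, MCL1 at -0.99 and TP53I3 at -0.90 on one side and IER2 at 1.07, PMEPA1 at 0.97 and BMAL1 at 0.80 on the other. NR3C1 was higher by 0.40. PER2 was lower by 0.98, a call that spike-in scaling lost (adjusted p = 0.0521). The calls of the 4 lists held under every scaling tried, and other scalings added lists. Ribosomal proteins were called lower with median centring (-0.28, adjusted p = 1.5e-13) and with trimmed-mean scaling (-0.27, adjusted p = 2.3e-14) but not with quantile scaling. Compared directly with non-treated cells, under quantile scaling alone, cells given mifepristone and dexamethasone differed at 66 probe sets, 48 higher and 18 lower. FKBP5 was still above the non-treated level by 1.28 (adjusted p = 5.1e-09), ANGPTL4 by 1.16, CIDEC by 1.04, TFCP2L1 by 0.94 and TSC22D3 by 0.55 (adjusted p = 0.011). CDKN1C at 0.23 (adjusted p = 0.80), DNAJC15 at 0.13 and RRAD at 0.02 did not pass the test.

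The match polyamide with dexamethasone was compared with dexamethasone alone to ask what a ligand of the response element does to the hormone-treated transcriptome. NR4A2 rose by 4.91 log2 units (SE 0.11; 17 to 972 in signal), RASD1, a Ras-related GTPase, by 3.51 (SE 0.21), the chemokine CCL20 by 3.19 (SE 0.20; 1 to 145), the trefoil peptide TFF1 by 3.12 (SE 0.12) and the ubiquitin-like interferon-induced protein ISG15 by 2.55 (SE 0.16). PIERCE2 (2.82, SE 0.14), LRATD2 (2.59, SE 0.11) and IER3 (2.53, SE 0.07) completed the 8 largest rises. The 8 largest falls were in ABTB3 (-3.76, SE 0.08; 1144 to 69), the lysine methyltransferase SMYD3 (-3.73, SE 0.15), the receptor phosphatases PTPRM (-3.64, SE 0.11) and PTPRK (-3.41, SE 0.11), DNAJC15 (-3.59, SE 0.21), the scaffold protein TANC2 (-3.52, SE 0.14), the contactin CNTN1 (-3.51, SE 0.11) and adenosine kinase ADK (-3.49, SE 0.15). FKBP5 fell by 2.28 (SE 0.07; 2706 to 546), CDKN1C by 1.71, and TSC22D3 by 0.70 (SE 0.09). ANGPTL4 was lower by 0.62 (SE 0.16, adjusted p = 0.0043), which spike-in scaling lost (-0.38, adjusted p = 0.145). DUSP1 was lower by 0.21 (SE 0.05, adjusted p = 0.0014), but not on the signals as deposited (adjusted p = 0.291), without a variance trend (0.0586) or with spike-in scaling (0.01 in log2 units, adjusted p = 0.961). SGK1 did not pass (0.26, SE 0.10, adjusted p = 0.054), although it passed in 9 settings, among them without match replicate 2 (0.0426), mifepristone replicate 1 (0.0413) or 3 (0.0161) or non-treated replicate 3 (0.0496). KLF9 did not pass either (-0.40, SE 0.18, adjusted p = 0.11; 0.0388 without a variance trend), nor did ZBTB16 (-0.09, SE 0.29, adjusted p = 0.86). CXCL8 rose by 0.96 (SE 0.21), and by 1.61 on its second probe set. Other probe sets of DUSP1 did not pass (-0.49, adjusted p = 0.133, and 0.37, adjusted p = 0.0853), those of TSC22D3 stood at -0.64 and at -0.02 (adjusted p = 0.965), and that of ANGPTL4 was lower by 0.81 (adjusted p = 0.00036).

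The match polyamide changed 12256 probe sets (30.8%), 6313 higher and 5943 lower, and among changes of at least 2-fold the falls outnumbered the rises, 1632 to 810. As deposited 7978 changed (4271 higher, 3707 lower), and with spike-in scaling 10885 (8217 and 2668). The glucocorticoid-induced list went down (3 of 33 higher, 19 lower, 11 not past the test; 4 and 19 when adjusted over the list alone; median -0.34, camera adjusted p = 2.7e-06). TFCP2L1 stood at -2.44, CIDEC at -2.44, TMT1A at -2.10, the acute phase gene SERPINA3 at -1.50 and the transcription factor CEBPD at -1.22, while CAVIN2 (0.60), TNFAIP3 (0.55) and ERRFI1 (0.25; adjusted p = 0.137 as deposited) rose. All 6 metallothioneins that dexamethasone had raised fell and 1 did not pass, with 0 higher and the same counts when adjusted over the list alone (median -1.35, adjusted p = 2.7e-06), MT1F at -1.90, MT1H at -1.86 and MT1X at -1.41. The inflammatory list went up in 11 of 22 members, with 2 lower and 9 not past the test (12 and 2 when adjusted over the list alone; median 0.54, adjusted p = 0.00096). PTGS2 stood at 1.78, while CCL2 fell by 1.02. CXCL2 was higher at 1.83 by its tested probe set, and a probe set that stood for it when no filter was applied did not pass (adjusted p = 0.999). The p53 list rose in 21 of 25 members, with 1 lower and 3 not past the test and the same counts when adjusted over the list alone (median 0.71, adjusted p = 6.9e-09). PPM1D and SESN2 rose by 1.40, MDM2, the ubiquitin ligase of p53, and SERTAD1 by 1.31, and the death receptors FAS and TNFRSF10B by 1.17 and 0.93. SPATA18 was lower by 0.53 (adjusted p = 0.0234), which was lost without dexamethasone replicate 1 (0.0955), without match replicate 1 (0.135) or 2 (0.0773), as deposited (0.124), with spike-in scaling (0.290) and with only the 6 arrays compared (0.0749). The ER stress and ATF4 list rose in 17 of 23 members with 4 lower and 2 not past the test and the same counts when adjusted over the list alone (median 0.90, adjusted p = 2.4e-07). ATF3 stood at 2.44, PPP1R15A at 1.97 and asparagine synthetase ASNS at 1.92. Immediate early genes rose in 15 of 24 members, with 1 lower and 8 not past the test (16 and 1 when adjusted over the list alone; median 0.60, adjusted p = 6.0e-07). DUSP6 (2.52), IER2 (1.74) and IER5 (1.29) were among its members. Interferon-stimulated genes rose in 13 of 19 members with 0 lower and 6 not past the test (14 and 0 when adjusted over the list alone; median 0.95, adjusted p = 3.3e-06). OAS1 (1.89), ISG20 (1.53) and IFIT3 (1.51) were among its members. TGF-beta and matrix genes fell in 14 of 20 members with 1 higher and 5 not past the test and the same counts when adjusted over the list alone (median -0.84, adjusted p = 2.4e-07). COL4A2 stood at -2.32, CCN2 at -1.60 and TGFBI at -1.19. All 8 lists passed with an estimated correlation as well (adjusted p from 0.001 to 0.028). These tests took no account of gene span, with which the changes under both polyamides varied. Cell cycle genes stood at the threshold, 14 of 30 higher, 3 lower and 13 not past the test (15 and 4 when adjusted over the list alone; median 0.17, adjusted p = 0.051, and 0.21 with an estimated correlation). CCNB2 stood at 0.71 and CDC20 at 0.59. That list passed without dexamethasone replicate 3 (0.0459), match replicate 1 (0.0329), mifepristone replicate 1 (0.0465) or 3 (0.0449) or mismatch replicate 2 (0.047) or 3 (0.0437). It passed too with the replicate number as a block. NRF2 targets went both ways (7 of 20 higher, 5 lower, 8 not past the test; 8 and 5 when adjusted over the list alone; adjusted p = 0.58), SRXN1 at 1.19 and ME1 at -1.46. Hypoxia genes did the same (6 of 20 higher, 6 lower, 8 not past the test; 7 and 6 when adjusted over the list alone; adjusted p = 0.93), VEGFA at 1.24 and CA12 at -0.97.

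**Figure D2:**
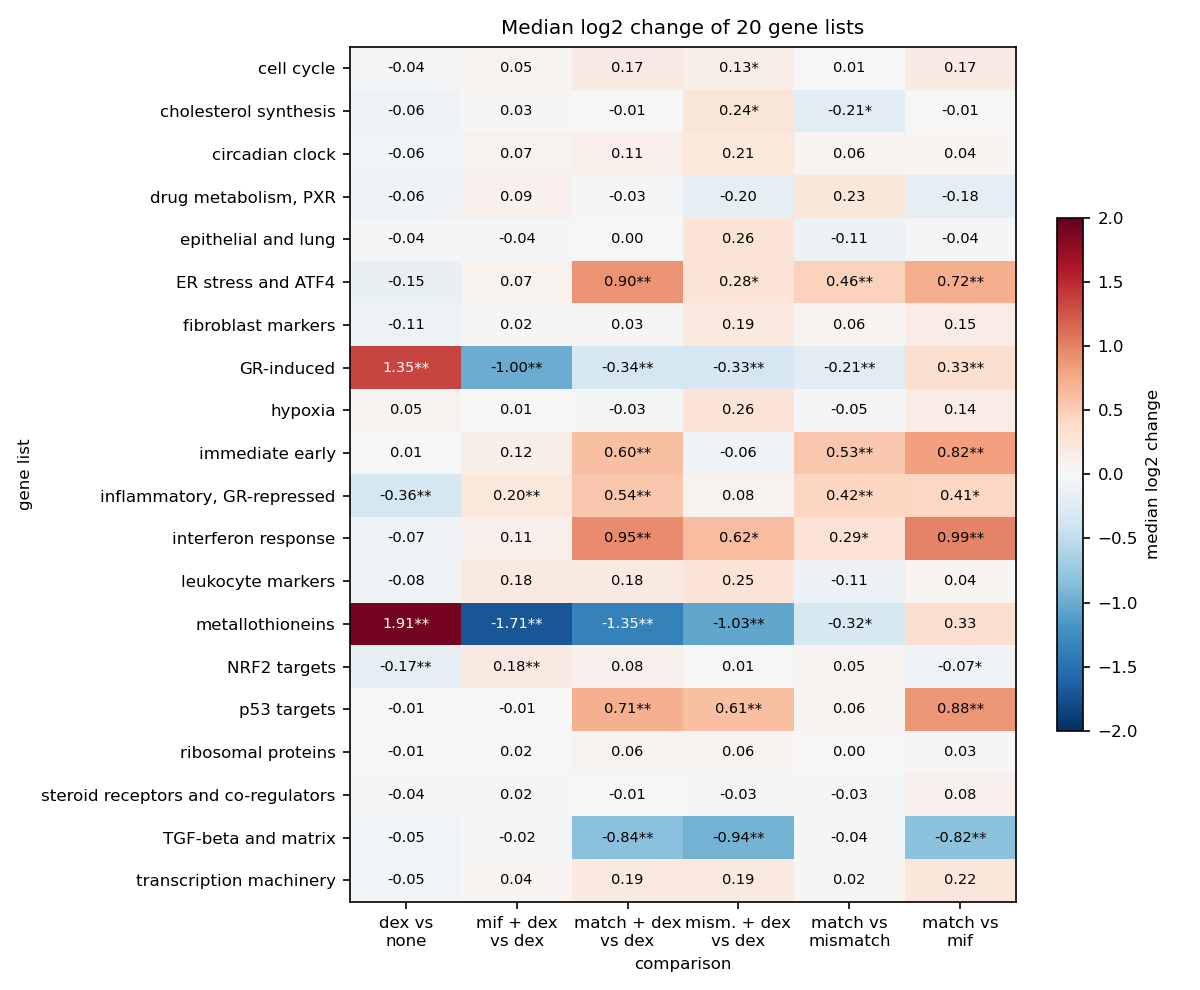
Median log2 change of the tested members of 20 gene lists in 6 comparisons; colour and number give the median, a single star marks a list called by camera with the preset correlation and a double star a list also called with an estimated correlation. The glucocorticoid-induced list had a median of 1.35 with dexamethasone and of -0.999, -0.34 and -0.33 when mifepristone, the match and the mismatch polyamide were added.

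The mismatch polyamide with dexamethasone was set against dexamethasone alone as the control ligand of the design. RASD1 rose by 3.61 log2 units (SE 0.21), BEX2 by 2.40 (SE 0.11), WFDC21P by 2.33 (SE 0.14), the neurofilament gene NEFL by 2.25 (SE 0.13), IER3 by 2.04 (SE 0.07), NR4A2 by 2.03 (SE 0.11; 17 to 118), CNNM4 by 1.93 (SE 0.23) and the MAP kinase phosphatase DUSP6 by 1.92 (SE 0.11). The 8 largest falls were in DOCK4 (-3.18, SE 0.12), the mitochondrial peptidase IMMP2L (-3.16, SE 0.13), the exocyst subunit EXOC4 (-3.11, SE 0.20), the glypican GPC6 (-3.02, SE 0.17), SMYD3 (-3.01, SE 0.15), protein kinase C alpha PRKCA (-2.87, SE 0.09), PTPRM (-2.81, SE 0.11) and LPP (-2.77, SE 0.11). FKBP5 fell by 0.84 (SE 0.07), from 2706 to 1501, while CDKN1C did not pass the test (-0.05, adjusted p = 0.846). TSC22D3 (-0.39, SE 0.09, adjusted p = 0.0042) and SGK1 (-0.41, SE 0.10, adjusted p = 0.0041) were lower, but neither call held on the signals as deposited (adjusted p = 0.535 for TSC22D3 and 0.471 for SGK1) or with spike-in scaling (0.347 for both). DUSP1 was lower by 0.22 (SE 0.05, adjusted p = 0.0018), a call lost as deposited (0.962), with median centring (0.108), with spike-in scaling (0.723) and without a variance trend (0.0699). ANGPTL4 (-0.48, SE 0.16, adjusted p = 0.033) lost its call in 10 settings, among them without dexamethasone replicate 1 (0.0661) or 3 (0.136) and without mismatch replicate 1 (0.0564) or 3 (0.168), but its second probe set was lower by 0.93 (adjusted p = 0.00015). The further probe sets of FKBP5 were lower by 1.69 and 1.10, whereas those of TSC22D3 (-0.41, adjusted p = 0.0693, and -0.05, adjusted p = 0.902) and DUSP1 (-0.46, adjusted p = 0.185, and 0.20, adjusted p = 0.435) did not pass. KLF9 (0.18, SE 0.18, adjusted p = 0.57), CXCL8 (-0.20, SE 0.21, adjusted p = 0.56) and ZBTB16 (-0.10, SE 0.29, adjusted p = 0.87) did not pass.

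The mismatch polyamide changed 9111 probe sets (22.9%), 4783 higher and 4328 lower, with 332 higher and 831 lower by at least 2-fold. It changed 6237 as deposited (4474 higher, 1763 lower) and 4624 with spike-in scaling (2645 and 1979). The glucocorticoid-induced list fell in 16 of 33 members, with 2 higher and 15 not past the test (18 and 2 when adjusted over the list alone; median -0.33, camera adjusted p = 7.2e-06). CIDEC stood at -1.66, TFCP2L1 at -0.91 and IGFBP1 at -0.78, while the sodium channel subunit SCNN1A rose by 1.29. CAVIN2 was higher by 0.45 (adjusted p = 0.0124), which was lost without dexamethasone replicate 2 (0.0537) or 3 (0.0683), without mismatch replicate 2 (0.0555) and without a variance trend (0.0586). Metallothioneins fell in 6 of 7 members, with 0 higher and 1 not past the test and the same counts when adjusted over the list alone (median -1.03, adjusted p = 8.9e-07). MT1H stood at -1.31 and MT1X at -1.08. The p53 list rose in 20 of 25 members, with 0 lower and 5 not past the test (21 and 0 when adjusted over the list alone; median 0.61, adjusted p = 7.2e-12). MDM2 stood at 1.30, PPM1D at 1.27, SESN2 at 1.21, TP53INP1 at 1.12, TNFRSF10B at 0.87 and CCNG1 at 0.61. TGF-beta and matrix genes fell in 15 of 20 members, with 1 higher and 4 not past the test and the same counts when adjusted over the list alone (median -0.94, adjusted p = 7.2e-12). Fibronectin FN1 stood at -1.98, COL4A2 at -1.66, TGFBI at -1.30 and LOXL2 at -1.07. These 4 lists passed with an estimated correlation (adjusted p from 0.00052 to 0.0035). Interferon-stimulated genes rose in 11 of 19 members, with 0 lower and 8 not past the test (14 and 0 when adjusted over the list alone; median 0.62, adjusted p = 2.1e-05, but adjusted p = 0.061 with an estimated correlation). ISG15 stood at 1.55, IFIT3 at 1.49 and OAS1 at 1.20. The ER stress and ATF4 list rose in 12 of 23 members with 4 lower and 7 not past the test (13 and 5 when adjusted over the list alone; median 0.28, adjusted p = 0.024, but 0.061 with an estimated correlation and 0.088 under the stricter filter). CHAC1 stood at 1.31, PCK2 at 1.16, CTH at 1.11 and ASNS at 1.06. Cholesterol synthesis genes rose in 7 of 15 members, with 0 lower and 8 not past the test (7 and 1 when adjusted over the list alone; median 0.24, adjusted p = 0.034, but 0.086 with an estimated correlation). ACAT2 stood at 0.65, INSIG1 at 0.63 and FDPS at 0.49. The cholesterol call was also lost with spike-in scaling (0.061) and without dexamethasone replicate 2 (0.0585) or mismatch replicate 3 (0.0704). Cell cycle genes rose in 8 of 30 members, with 0 lower and 22 not past the test (9 and 0 when adjusted over the list alone; median 0.13, adjusted p = 0.021, but 0.15 with an estimated correlation, 0.12 with the median of the probe sets of a gene and 0.083 under the stricter filter). CDC6 stood at 0.53. The inflammatory list was not called (6 of 22 higher, 3 lower, 13 not past the test; 7 and 3 when adjusted over the list alone; adjusted p = 0.43). RELB stood at 1.26 and PTGS2 at 0.95. The immediate early list was not called either (9 of 24 higher, 7 lower, 8 not past the test; 10 and 7 when adjusted over the list alone; median -0.06, mean 0.24, adjusted p = 0.44). FOSL1 stood at 1.15 and IER5 at 0.70.

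Of the 372 probe sets that dexamethasone had changed at least 2-fold, 319 (85.8%) were moved back by mifepristone with a passed test, 244 of the 290 raised and 75 of the 82 lowered, and 0 were moved further. The match polyamide moved back 263 (70.7%), 215 raised and 48 lowered, and moved 20 further, and the mismatch polyamide moved back 201 (54.0%), 170 raised and 31 lowered, and moved 40 further. Where the compound was simulated to change nothing, 2.15, 8.3 and 7.25 probe sets counted as moved back on average over 20 simulations for mifepristone, match and mismatch, and 6.95, 56.4 and 41.4 would be shared by independent lists of these sizes. Over genes rather than probe sets, the 139 genes raised at least 2-fold by dexamethasone changed by medians of -1.15 with mifepristone, -0.95 with the match and -0.42 with the mismatch polyamide. The 55 genes lowered at least 2-fold changed by medians of 1.01, 0.52 and 0.24. The same dexamethasone arrays entered both the selection and the compound comparison, which the simulation takes into account. Any called change the opposite way counts as moved back, whatever its size. The counts therefore mix full reversal with small shifts and with overshoot. With match, DUSP1 counted at -0.21 after a rise of 1.40. NR4A2, which dexamethasone had lowered, counted at 4.91 with match, which took it above the non-treated level.

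**Figure D3:**
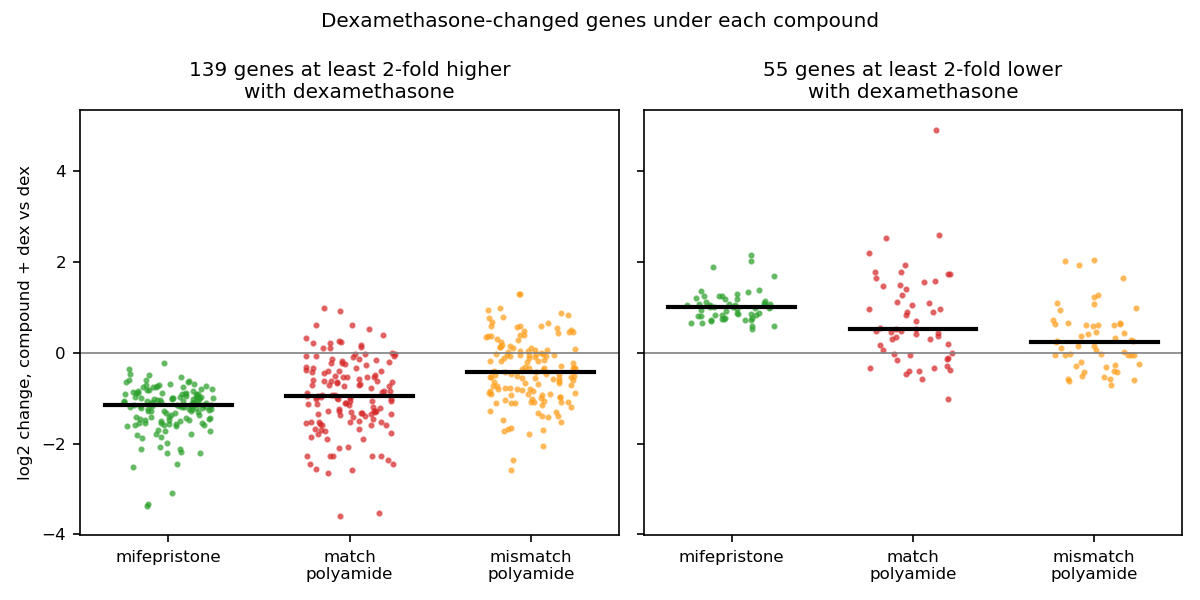
Log2 change with each compound plus dexamethasone against dexamethasone alone for the 139 genes that dexamethasone raised and the 55 that it lowered at least 2-fold; points are genes and the bar is the median. Medians of the raised genes were -1.15, -0.95 and -0.42 for mifepristone, match and mismatch.

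The direct comparison of the match with the mismatch polyamide, both with dexamethasone, asked which changes differed between the ligands. NR4A2 was higher with match by 2.89 log2 units (SE 0.11), CCL20 by 2.69 (SE 0.20), CARD8-AS1 by 1.99 (SE 0.21), the gastrokine GKN2 by 1.76 (SE 0.28), the helicase DDX10 by 1.69 (SE 0.09), TFF1 by 1.68 (SE 0.12) and the phosphatase DUSP5 by 1.60 (SE 0.08). CXCL2 was higher by 1.72 (SE 0.13) with its tested probe set, and the probe set that stood for it without a filter did not pass (adjusted p = 0.976). The largest differences downwards were in DNAJC15 (-2.27, SE 0.21), CNTN1 (-2.01, SE 0.11), the kidney cadherin CDH16 (-1.94, SE 0.25), the troponin TNNC1 (-1.92, SE 0.30), DKK3, a secreted protein of the Dickkopf family (-1.90, SE 0.09), the serine protease HTRA1 (-1.89, SE 0.20), SLC22A17 (-1.80, SE 0.21) and the arrestin ARRB1 (-1.72, SE 0.11). Those of TNNC1 and SLC22A17 were mainly rises with mismatch. Against dexamethasone alone these genes stood at 1.91 and 1.41 with mismatch and at -0.01 and -0.39 with match. The others named here were lower with match than with dexamethasone alone. Among the hormone's targets, CDKN1C was lower with match by 1.66 (SE 0.12), TFCP2L1 by 1.53 (SE 0.11), FKBP5 by 1.43 (SE 0.07), CIDEC by 0.78 and CEBPD by 0.69 (SE 0.07). Of the further FKBP5 probe sets, 1 was lower by 1.32 and 1 did not pass (-0.65, adjusted p = 0.0748). SGK1 was higher with match by 0.67 (SE 0.10, adjusted p = 6.9e-05; 0.0591 as deposited), and CXCL8 by 1.17 (SE 0.21; 1.89 on its second probe set). DUSP1 was not called different (0.00, 95% CI -0.09 to 0.10, adjusted p = 0.97), and ANGPTL4 did not pass (-0.14, 95% CI -0.47 to 0.19, adjusted p = 0.63). TSC22D3 was lower by 0.31 (SE 0.09, adjusted p = 0.027), but its call was lost without match replicate 1 (0.0909) or 3 (0.0504), without mismatch replicate 1 (0.0719), 2 (0.0553) or 3 (0.0802), as deposited (0.0909), without a variance trend (0.079) and with spike-in scaling (0.59). KLF9 (-0.58, SE 0.18, adjusted p = 0.035) lost its call in 11 settings, among them without match replicate 1 (0.0955) or 3 (0.0984) and mismatch replicate 2 (0.125) or 3 (0.0954). Further probe sets of TSC22D3 (-0.23, adjusted p = 0.372, and 0.03, adjusted p = 0.936) and KLF9 (-0.35, adjusted p = 0.432) did not pass, and no other probe set of DNAJC15 or SLC22A17 was called. NR3C1 was lower with match by 0.48 (SE 0.08; 0.222 as adjusted p with spike-in scaling).

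Match and mismatch differed at 6695 probe sets (16.8%), 2969 higher with match and 3726 lower, of which 155 and 281 differed at least 2-fold. The balance turned with array scaling, from 556 higher and 2538 lower as deposited to 2135 higher and 712 lower with spike-in scaling. Immediate early genes were higher with match in 20 of 24 members, with 0 lower and 4 not past the test and the same counts when adjusted over the list alone (median 0.53, camera adjusted p = 6.6e-16). IER2 stood at 1.09 and MYC at 0.82. The ER stress and ATF4 list was higher in 15 of 23 members with 0 lower and 8 not past the test (16 and 0 when adjusted over the list alone; median 0.46, adjusted p = 7.6e-12). PPP1R15A stood at 1.32, TRIB3 at 1.06 and ASNS at 0.87. The inflammatory list was higher in 11 of 22 with 0 lower and 11 not past the test (11 and 1 when adjusted over the list alone; median 0.42, adjusted p = 2.2e-06). CXCL3 stood at 1.33 and PTGS2 at 0.83. These 3 lists passed with an estimated correlation (adjusted p up to 0.0037). The glucocorticoid-induced list was lower with match in 16 of 33 members, with 3 higher and 14 not past the test (16 and 6 when adjusted over the list alone; median -0.21, adjusted p = 0.012, and 0.029 with an estimated correlation), but not with the median of the probe sets of a gene (0.054) or under the stricter filter (0.085). Interferon-stimulated genes were higher in 5 of 19 members with 0 lower and 14 not past the test (5 and 1 when adjusted over the list alone; median 0.29, adjusted p = 0.012, but 0.25 with an estimated correlation and 0.053 without mismatch replicate 3). ISG15 stood at 1.00 and OAS1 at 0.70. Metallothioneins were lower in 4 of 7 with 0 higher and 3 not past the test and the same counts when adjusted over the list alone (median -0.32, adjusted p = 0.019, but 0.072 with an estimated correlation). MT1F stood at -0.87. Cholesterol synthesis genes were lower in 5 of 15 with 0 higher and 10 not past the test (6 and 0 when adjusted over the list alone; median -0.21, adjusted p = 0.043, but 0.11 with an estimated correlation, 0.15 with spike-in scaling, 0.073 with the median of the probe sets of a gene and 0.091 under the stricter filter). That call was also lost without match replicate 3 (0.0737) or mismatch replicate 3 (0.0929). The p53 list was not called (4 of 25 higher, 3 lower, 18 not past the test, and the same when adjusted over the list alone; median 0.06, adjusted p = 0.39). MDM2 stood at 0.01 (95% CI -0.21 to 0.23), PPM1D at 0.13 (95% CI -0.01 to 0.27) and TNFRSF10B at 0.06 (95% CI -0.08 to 0.21), and none of these 3 passed, while PLK3 (0.83) and XPC (0.53) were higher with match and TP53INP1 was lower (-0.54). The XPC call was lost as deposited and that of TP53INP1 with spike-in scaling. The TGF-beta and matrix list was not called (3 of 20 higher, 6 lower, 11 not past the test, and the same when adjusted over the list alone; adjusted p = 0.87), but its members went both ways, with PMEPA1 (1.13) and FN1 (0.49) higher and COL4A2 (-0.66) and CCN2 (-0.55) lower. Spike-in scaling lost the calls of COL4A2 and CCN2, and the signals as deposited that of FN1. Several of the genes most changed by mismatch were not called different either. RASD1 stood at -0.10 (95% CI -0.54 to 0.34), BEX2 at 0.03 (95% CI -0.19 to 0.25), NEFL at 0.04 (95% CI -0.24 to 0.31), EXOC4 at -0.01 (95% CI -0.42 to 0.41) and DOCK4 at -0.08 (95% CI -0.33 to 0.16), and none of these 5 passed. PTPRM was lower with match by 0.83. Over the 290 probe sets that dexamethasone raised at least 2-fold, the median difference of match from mismatch was -0.40, with 134 lower and 17 higher (camera p = 1.2e-18, and 6.0e-06 with an estimated correlation). Over the 82 lowered it was 0.44, with 41 higher and 3 lower (p = 3.8e-20, and 1.0e-05 with an estimated correlation).

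Changes under the ligands were compared with each other over all tested probe sets. Both polyamides raised 3272 probe sets and lowered 3347, where independent lists would share 760 and 647, and 124 went opposite ways. Of the probe sets changed by mismatch, 72.6% were changed the same way by match, and the log2 changes correlated at r = 0.757. Simulated compounds without an effect gave r = 0.501 through the shared dexamethasone arrays. Their covariance was 0.019 against 0.167 in the data, so the shared arrays gave only a small part of the agreement. On disjoint arrays, match against mifepristone and mismatch against non-treated, the correlation was r = 0.634 (Spearman 0.502), with 2562 probe sets higher and 3122 lower in both, where 650 and 643 would be shared by independent lists. Both contrasts also hold the part of the dexamethasone response that the polyamides left. Part of this agreement can therefore come from the hormone. The match changes were 1.27 times as spread as the mismatch changes.

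The match polyamide was also compared directly with mifepristone, both with dexamethasone. FKBP5 was not called different (-0.08, 95% CI -0.22 to 0.07, adjusted p = 0.47; mean signals 546 and 576), although on the signals as deposited it was lower with match (-0.48, adjusted p = 0.0201). TSC22D3 was higher with match by 1.75 (SE 0.09; 661 against 187), CAVIN2 by 2.19 (SE 0.13), RGS2 by 1.53 (SE 0.09), SGK1 by 1.46 (SE 0.10), ANGPTL4 by 1.46 (SE 0.16), ERRFI1 by 1.37 (SE 0.05) and DUSP1 by 0.63 (SE 0.05). KLF9 (0.52, SE 0.18, adjusted p = 0.037) lost its call in 10 settings, among them without match replicate 1 (0.0551), 2 (0.13) or 3 (0.0522) and mifepristone replicate 2 (0.16) or 3 (0.0818). CXCL8 (0.64, SE 0.21, adjusted p = 0.024) did so in 7, among them without match replicate 1 (0.103) or 2 (0.0663) and mifepristone replicate 1 (0.0583) or 3 (0.112), but its second probe set was higher by 1.11 (adjusted p = 0.00016). Further probe sets of KLF9 (0.00, adjusted p = 0.994) and TSC22D3 (0.30, adjusted p = 0.277) did not pass, and another of TSC22D3 was higher by 1.36. ZBTB16 did not pass (0.23, SE 0.29, adjusted p = 0.62). The largest rises were in NR4A2 (3.83, SE 0.11), RASD1 (3.34, SE 0.21), CCL20 (3.21, SE 0.20), TFF1 (2.95, SE 0.12), RRAD (2.69, SE 0.18), GKN2 (2.57, SE 0.28), PIERCE2 (2.38, SE 0.14) and the complement regulator CD55 (2.31, SE 0.07). The largest falls were in CNTN1 (-3.80, SE 0.11), SMYD3 (-3.64, SE 0.15), PTPRK (-3.60, SE 0.11), IMMP2L (-3.51, SE 0.13), the calcium channel subunit CACNA2D1 (-3.49, SE 0.13), PTPRM (-3.47, SE 0.11), ADK (-3.47, SE 0.15) and LPP (-3.34, SE 0.11), and the other probe set of PTPRK was not called.

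In all, 12316 probe sets (31.0%) differed between match and mifepristone, 6276 higher with match and 6040 lower, of which 766 and 1517 differed at least 2-fold. This even split did not hold on the signals as deposited (1264 higher, 9512 lower) or with spike-in scaling (1895 and 7054). The glucocorticoid-induced list was higher with match in 16 of 33 members with 4 lower and 13 not past the test (17 and 4 when adjusted over the list alone; median 0.33, camera adjusted p = 9.8e-05). SERPINA3 (-1.04), TMT1A (-0.96), PDK4 (-0.77) and CIDEC (-0.45; adjusted p = 0.0664 without mifepristone replicate 2) were the lower ones. Higher with match was the p53 list (20 of 25 higher, 1 lower, 4 not past the test; 21 and 1 when adjusted over the list alone; median 0.88, adjusted p = 3.3e-11), with GADD45A at 1.82 and TP53I3 at 1.06. So was the immediate early list (16 of 24 higher, 2 lower, 6 not past the test, and the same when adjusted over the list alone; median 0.82, adjusted p = 2.5e-08). KLF4 stood at 2.21 and DUSP6 at 2.02. The same held for the ER stress and ATF4 list (15 of 23 higher, 3 lower, 5 not past the test; 16 and 3 when adjusted over the list alone; median 0.72, adjusted p = 1.9e-06). ASNS stood at 1.85 and TRIB3 at 1.49. Interferon-stimulated genes were higher too (13 of 19 higher, 0 lower, 6 not past the test, and the same when adjusted over the list alone; median 0.99, adjusted p = 3.5e-06). ISG15 stood at 2.22 and IRF7 at 1.70. TGF-beta and matrix genes were lower with match (1 of 20 higher, 14 lower, 5 not past the test, and the same when adjusted over the list alone; median -0.82, adjusted p = 1.7e-06). COL4A2 stood at -2.19, FN1 at -1.74 and TGFBI at -1.22. With an estimated correlation those 6 lists passed (adjusted p from 0.0006 to 0.035). The inflammatory list was higher in 11 of 22 with 4 lower and 7 not past the test (12 and 4 when adjusted over the list alone; median 0.41, adjusted p = 0.029, but 0.096 with an estimated correlation, 0.051 without a filter and 0.052 under the stricter filter). RELB stood at 1.80 and IER3 at 1.29. NRF2 targets were lower in 9 of 20 with 4 higher and 7 not past the test (9 and 5 when adjusted over the list alone; median -0.07, adjusted p = 0.02, but 0.12 with an estimated correlation and 0.16 with spike-in scaling), with ME1 at -1.69. Their median turned to 0.07 with median centring (adjusted p = 0.53) and to 0.09 with trimmed-mean scaling (0.64). Metallothioneins did not pass (2 of 7 higher, 0 lower, 5 not past the test; 4 and 0 when adjusted over the list alone; median 0.33, adjusted p = 0.24).

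Lists for other cell types and for general functions were tested in the same way and were not called with the match polyamide against dexamethasone. Leukocyte markers were higher in 3 of 11 members with 0 lower and 8 not past the test (3 and 0 when adjusted over the list alone; adjusted p = 0.43). CORO1A, an actin-binding protein of leukocytes, stood at 1.99 and the integrin ITGAM at 0.88. Fibroblast markers were higher in 1 of 12, collagen COL1A1 at 1.01, lower in 2, among them S100A4 at -0.74, and not past the test in 9 (1 and 2 when adjusted over the list alone; adjusted p = 0.88). Ribosomal proteins were higher in 7 of 30 with 0 lower and 23 not past the test (7 and 0 when adjusted over the list alone; adjusted p = 0.10), RPL12 at 0.43 the largest change among them. Clock genes were higher in 4 of 16, CRY1 (0.72) and PER2 (0.52) among them, lower in 2, with NR1D2 at -0.84, and not past the test in 10 (5 and 3 when adjusted over the list alone; adjusted p = 0.76). Cholesterol synthesis genes were higher in 3 of 15, INSIG1 at 0.79 among them, lower in 3 and not past the test in 9 (3 and 3 when adjusted over the list alone; adjusted p = 0.92). Drug metabolism genes were higher in 1 of 10, lower in 0 and not past the test in 9 (1 and 0 when adjusted over the list alone; adjusted p = 0.92).

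The span of each gene from start to end, from the RefSeq annotation of GRCh38.p14, was compared with its log2 change after the strongest falls under the polyamides had been seen. The 8 genes most lowered by match had a median span of 507 kb and those most lowered by mismatch 799 kb, against 26.9 kb over all genes. Over 16334 genes the Spearman correlation of span with log2 change was -0.310 for match and -0.288 for mismatch, against 0.038 for mifepristone and -0.014 for dexamethasone. Genes over 300 kb changed by medians of -0.49 with match and -0.39 with mismatch, 48.9% and 44.5% of these 616 genes being called lower, while genes under 10 kb changed by 0.14 with either polyamide. With mifepristone the medians of the 5 span classes lay between 0.01 and 0.03. The difference of match from mismatch correlated with span at -0.156 and that of match from mifepristone at -0.331. The list tests compare members with all other genes whatever their span. Shifts of lists in the comparisons that hold a polyamide may therefore follow gene length in part, which was not tested.

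**Figure D4:**
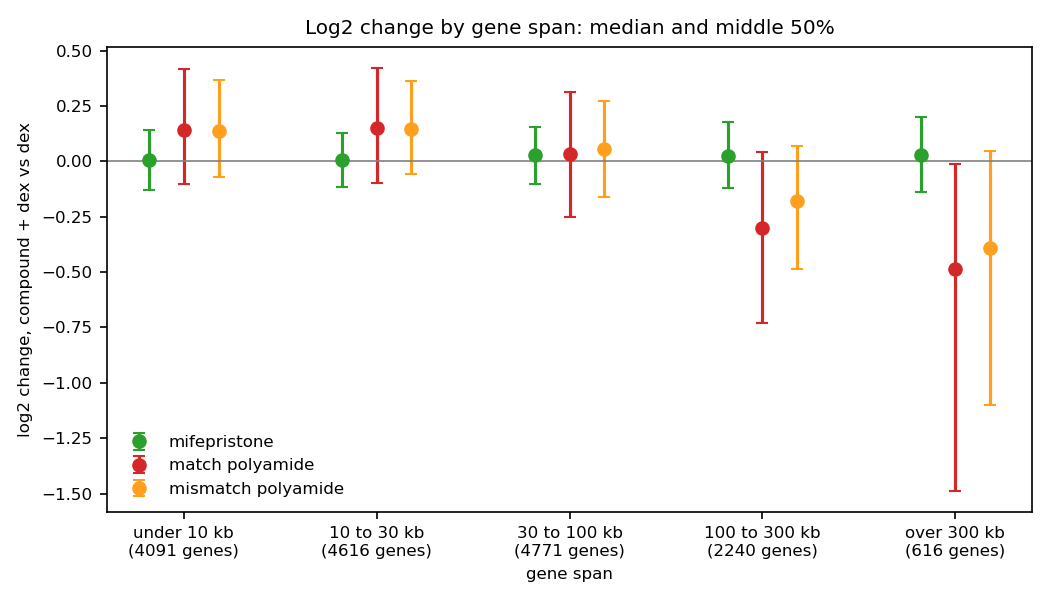
Median log2 change by class of gene span for 3 compounds with dexamethasone against dexamethasone alone; points are medians over 616 to 4771 genes per class and bars hold the middle 50% of genes. Medians fell to -0.49 and -0.39 in the class over 300 kb for match and mismatch and stayed near 0.03 for mifepristone.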

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

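The control probe sets were examined after the comparisons had been made, as values without a test, since the comparisons leave these probe sets out. A control probe set for the 5' part of 28S ribosomal RNA gave more signal on every polyamide array than on any of the 6 non-treated and dexamethasone arrays, a signal in data that the comparisons do not use. Its log2 signal was above the mean of those 6 arrays by 1.65 with the match and 0.79 with the mismatch polyamide, with mean deposited signals, before scaling, of 6838 and 4366 against 2375 for non-treated and 1861 for dexamethasone. With mifepristone the difference was -0.14, but its arrays spread widely (SD 1.30, 3 arrays, mean deposited signal 3055). The control probe set for the middle part of the same RNA differed by 0.19 and 0.11 with match and mismatch, and that for the 3' part, at low signal, by -0.16 and 0.36. For neither did every polyamide array lie above the 6 others. Groups of 3 arrays were not tested for single arrays far from the rest.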

How the results depend on the processing

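Among the tests in this part, the signals as deposited, the trimmed-mean scaling and the spike-in scaling were chosen after the results had been seen. No named gene or list turned its direction with a passed test, but the balance of higher and lower probe sets turned under some scalings. Over all settings, single genes picked by the naming rule or quoted in the text gave 16769 values on the same side of the threshold, 487 that lost the call and 117 that gained it, and lists gave 3302, 29 and 29.

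On the signals as deposited, 814 probe sets changed with dexamethasone (69.3% higher), 8142 with mifepristone (97.2% higher), 7978 with match, and 3094 differed between match and mismatch (17.97% higher with match), and 7 lists shifted with mifepristone. With spike-in scaling the counts were 767 for dexamethasone, 12838 for mifepristone (98.3% higher), 4624 for mismatch and 2847 for match against mismatch (74.99% higher), and 7 lists shifted with mifepristone. The mifepristone arrays were brighter as a group, and the median of all probe sets moved from 0.01 with quantile scaling to 0.35 as deposited and 0.40 with spike-in scaling in that comparison; for the other counts the cause was not tested. Whether cells given mifepristone held more RNA cannot be read from these scalings. Other shares of raised probe sets that moved were 33.6% with median centring for match against mismatch, 71.7% as deposited for mismatch, 75.5% with spike-in scaling for match, and 11.7% as deposited and 21.2% with spike-in scaling for match against mifepristone.

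With a pseudocount of 64, 183, 145 and 115 of 185 selected probe sets were moved back by mifepristone, match and mismatch, with a pseudocount of 1 391, 350 and 268 of 565, and with selection at 1.5-fold 763, 657 and 531 of 1094, against 319, 263 and 201 of 372. The share moved back was thus larger with the higher pseudocount and smaller with the lower one and at 1.5-fold. With an estimated correlation 4 lists shifted with mismatch and 4 between match and mismatch. Leaving out 1 array at a time gave 1432 to 2033 changed probe sets for dexamethasone, 1003 to 1483 for mifepristone, 10807 to 12320 for match, 7505 to 9348 for mismatch, 5370 to 6741 for match against mismatch and 10684 to 12334 for match against mifepristone. The lists shifted numbered 4 to 4, 4 to 4, 8 to 9, 7 to 9, 5 to 7 and 8 to 8 in the same order. Moved back were 290 to 325, 246 to 289 and 174 to 233 by mifepristone, match and mismatch, and the median differences of match from mismatch were -0.398 to -0.294 over raised and 0.322 to 0.496 over lowered probe sets.

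Replicate numbers gave no clear pairing of the arrays, but weak pairing is not excluded. Deviations from the group means correlated at -0.084 to 0.117 for the same number and at -0.132 to 0.135 for different numbers, which overlap. However, 8 of 15 arrays correlated best with their own number, more than an even share over the numbers. With the number as a block, 1922, 1431, 12239, 9111, 6716 and 12311 probe sets changed. Of the results named in the text the block moved SGK1 (adjusted p = 0.0217), CREBBP (0.0333) and the cell cycle list (0.0483) with match against dexamethasone past the threshold, and no other.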

Other observations

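The tests over the upper 4 of 5 signal classes and under the as-deposited, trimmed-mean and spike-in scalings were chosen after results had been seen. The co-activator genes NCOA2 and NCOA1 were lower with both polyamides than with dexamethasone alone. NCOA2 was lower by 1.73 (SE 0.09, 3 arrays per group) with match and by 1.04 (SE 0.09) with mismatch, and differed between them by -0.69 (SE 0.09), and NCOA1 was lower by 1.16 (SE 0.13) and 0.88 (SE 0.13). The glucocorticoid receptor NR3C1 was lower by 0.75 (SE 0.08) with match. With mismatch NR3C1 stood at -0.27 (limma adjusted p = 0.0152), a call lost without dexamethasone replicate 1 (0.0948) or 3 (0.0538), without mismatch replicate 2 (0.0613), as deposited (0.886), with median centring (0.0836), with spike-in scaling (0.679) and without a variance trend (0.0773). The chaperone FKBP4 was higher by 0.53 with match and 0.42 with mismatch, and STIP1 by 0.51 with match. The list of steroid receptors and co-regulators as a whole was not called, with 3 of 15 higher, 4 lower and 8 not past the test for match (3 and 5 when adjusted over the list alone; camera adjusted p = 0.58) and 2 higher, 5 lower and 8 not past the test for mismatch (4 and 5 when adjusted over the list alone; adjusted p = 0.36). CREBBP and NRIP1 were lower with mismatch (-0.66 and -0.49) but did not pass with match (-0.26, adjusted p = 0.0564, and -0.13, adjusted p = 0.264), and both differed between the polyamides (adjusted p = 0.0090 and 0.0037). These calls were lost on the signals as deposited, and CREBBP passed with match in 5 settings. Transcripts of long genes fell with both polyamides. Of all genes of 100 to 300 kb, 43.7% were called lower with match and 32.2% with mismatch. Whether the falls of NCOA2, NCOA1 and NR3C1 follow gene span was not tested.

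Epithelial genes went both ways under the polyamides. The adhesion protein EPCAM was higher by 1.76 (SE 0.11) with match and 1.46 (SE 0.11) with mismatch, and ELF3 (1.06 and 0.83) and the keratin KRT19 (0.69 and 0.59) rose as well, while E-cadherin CDH1 was lower by 1.499 (SE 0.10) and 1.17 (SE 0.10). The epithelial and lung list was not called (5 of 19 higher, 8 lower, 6 not past the test for match, 6 and 8 when adjusted over the list alone, adjusted p = 0.88; 6, 3 and 10 for mismatch, 7 and 4 when adjusted over the list alone, adjusted p = 0.64). Partners in the CDK-activating kinase of transcription factor TFIIH went opposite ways with match, CDK7 at 1.33 (SE 0.09) and MNAT1 at -1.23 (SE 0.11). With mismatch CDK7 was higher by 0.63 (SE 0.09) and MNAT1 lower by 0.59 (adjusted p = 0.103 as deposited). Whether these changes of CDK7 and MNAT1 follow gene span was not tested. The transcription machinery list had 11 of 28 higher, 3 lower and 14 not past the test for match (12 and 4 when adjusted over the list alone; adjusted p = 0.11) and 10, 1 and 17 for mismatch (10 and 1 when adjusted over the list alone; adjusted p = 0.065), and it passed for mismatch without dexamethasone replicate 3 (0.0391) or mismatch replicate 2 (0.0386).

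Both polyamides lowered the transcripts of long genes more than those of short genes. Quantile normalization did not create this trend, since the signals as deposited gave correlations of span with log2 change of -0.31 with match and -0.28 with mismatch. The other scalings multiply each array by a single factor, which hardly changes the order of genes. Their agreement (weakest -0.28 over all 5 scalings) therefore tests little. RNA degradation as read from the 5' to 3' ratios of actin and GAPDH does not account for the trend. The polyamide arrays with both ratios in the range of the other 9 arrays had trends of -0.323 and -0.299, and those with a GAPDH ratio above that range, which points away from degradation, -0.302 and -0.290. Match replicate 2 and mismatch replicate 2 had log2 actin ratios of -0.781 and -0.990, which points towards degradation. The lowest of the other 9 arrays was -0.654. These replicates had trends of -0.307 and -0.267. Signal level was tested within 5 equal classes of the genes by mean signal. It does not account for the trend in the upper 4 classes, where the correlations from low to high signal were -0.19, -0.47, -0.49 and -0.38 with match and -0.17, -0.47, -0.48 and -0.35 with mismatch. It stays open only for the lowest class (-0.050 and -0.027), whose median signal of 10.4 lies near the floor. An effect of the polyamides is consistent with all 6 polyamide arrays having trends of -0.323 to -0.267 against -0.0702 to 0.0931 for the other 9 and with 0.038 for mifepristone. Whether slower transcription through long genes may lie behind it was not tested, and the design held no polyamide without dexamethasone.

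Over the 139 genes that dexamethasone raised, the further fall with match than with mismatch could in part follow gene length. The changes of these genes against dexamethasone alone correlated with span at -0.40 with match and -0.32 with mismatch. The difference between the polyamides correlated with span at -0.17 over these genes (permutation p = 0.0484, 100000 permutations), between the bounds set for a clear answer either way. The test cannot tell whether length is behind the difference. Nor can the sequence bound be told apart from the doses, which are not given in the sources used here. Over all tested probe sets the match changes were also 1.27 times as spread as the mismatch changes.

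All splits of the 6 arrays of a comparison into 3 and 3 were run, 10 each, which are too few for a share under 0.05. Each of the other splits mixes the groups compared. The real difference then widens the spread between arrays, and part of it stays in the contrast. Counts of the other splits are therefore not those of unchanged groups. The real grouping gave 1933, 1412, 12256, 9111, 6695 and 12316 changed probe sets for dexamethasone, mifepristone, match, mismatch, match against mismatch and match against mifepristone, and the highest of the other splits gave 0, 1, 0, 0, 1 and 0, so that 1 split of 10 reached the count in each. For lists the real grouping gave 4, 4, 8, 8, 7 and 8, the highest other split 5, 5, 9, 5, 4 and 7, and 4, 2, 2, 1, 1 and 1 splits of 10 reached the real count. For probe sets moved back the values were 319, 263 and 201 against 0, 0 and 0, with 1 split of 10 in each. The median differences of match from mismatch had sizes of 0.396 and 0.445 over raised and lowered probe sets, against 0.180 and 0.189 in the highest other split, with 1 split of 10 in each.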
